A study of Homo sapiens with 24 samples.

How the data were processed

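Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in HCC827, a human lung adenocarcinoma line with mutated and amplified EGFR. The cells were parental or resistant to osimertinib, an inhibitor of mutant EGFR, and resistant cells were kept in 1 µM of the drug, per the labels. In both states, wild-type cells and cells expressing METTL7A fused to MYC and FLAG tags were precipitated with an IgG isotype control or with an antibody to the MYC tag. The titles of the tagged cells read M7A_OE, taken here as overexpression. These cells are called METTL7A-expressing below, and the METTL7A level of wild-type cells was not measured here. METTL7A is a membrane-associated methyltransferase-like protein, listed as TMT1A in the GRCh38.p14 gene table. The tag is a stretch of the human MYC protein, so the antibody can also bind MYC itself in wild-type cells. The series holds 24 samples in 12 groups of 2, labelled as biological replicates. Of these, 16 samples in 8 groups entered the 8 peak lists used here, and the 8 input samples in 4 groups have no peak list of their own among the files used.

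Chromatin was made with a ChIP-IT Express kit and sheared by Covaris sonication, libraries were built with an EpiCypher CUT&RUN library kit, and sequencing on an Illumina NovaSeq instrument was planned at 20 M paired-end reads per library, per the labels. The submitters' processing notes name Trimmomatic, FastQC, Bowtie2 2.4.2, SAMtools 1.16, MACS2 2.2.7.1, deepTools 3.5.1, bedtools 2.30 and the genome build GRCh37, with no role or order. The library that served as control in peak calling, duplicate removal, blacklist filters and the version of the reproducibility tool are not given in the sources used here. Peak lists hold no read totals, so the depth of each library is unknown from the files.

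Each deposited list has 20 columns in the layout of the irreproducible discovery rate (IDR) method, which matches peaks of 2 replicates by position and rank. The authors' score in column 5 is a scaled IDR that reaches 1000, and peaks were selected on the global IDR of the same line instead. Peak heights are −log10 p-values of the peak caller, deposited by the authors for each of the 2 replicates, and the global IDR is also stored as −log10. Heights are the authors' values, are not on a common scale across lists, and served to rank, filter or describe peaks. For positions found in all 4 wild-type lists the highest of the 4 heights was used, and the comparison was repeated within each list. Nothing in a list says which replicate fills which set of columns. "Matched peaks" below means all peaks of a list, whose lowest −log10 p was 3.00. "Reproducible peaks" means those at a global IDR of 0.05 or less. The height given for a peak is the lower of its 2 replicates' −log10 p. One list combines both replicates of a group, so a list has no replicate error of its own. Every p-value below therefore compares lists of peaks and does not measure the spread between replicate cultures.

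An IDR threshold adapts to each list. The lowest −log10 p among reproducible peaks was 3.18 in the parental METTL7A IgG list and 4.98 in the resistant METTL7A IgG list, against 7.15 to 12.9 in the other 6. Counts of reproducible peaks from these lists do not rest on one common height. Peak numbers also rise with depth and enrichment, and with the copy number of the DNA, since a region present in more copies gives more reads from any library.

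Overlaps between lists were counted at a minimum of 1 bp. Each was set against 1000 random placements of the first list's peaks, at the same widths and within the same chromosome, as a one-sided permutation test for more overlap than chance. Tests were adjusted by the Benjamini-Hochberg method within families of 4 (MYC-tag against IgG), 2 (METTL7A against wild-type) and 4 (resistant against parental). The smallest p-value that the placements can give is 0.001. Placement ignored assembly gaps and mappability, because no GRCh37 sequence was used here. METTL7A-specific peaks were MYC-tag peaks of METTL7A-expressing cells that overlapped no peak of the wild-type MYC-tag list and of either IgG list in the same cell state. Shares of peaks carry exact (Clopper-Pearson) 95% binomial intervals. These cover counting error only, and neighbouring peaks are not independent. Shares on chromosome 7 were compared by 8 two-sided Fisher exact tests. The effect of the antibody on that share was compared between genotypes, once per cell state, by Zelen's two-sided exact test of equal odds ratios. This test was added after the data were seen, and replaced a Wald test that had been run first, because some lists hold few peaks. Printed odds ratios carry Haldane's correction for small counts. Matched peaks in 10 regions were tested over 10 list pairs by 100 two-sided Fisher exact tests, adjusted as 1 family. All these exact tests treat neighbouring peaks as independent, so their p-values can be too small where peaks cluster. The bins of MET, MYC and METTL7A followed from the naming rule, and the other 7 regions were chosen after the peak positions were seen. The genome's span is the sum over chromosomes of the distance between the first and the last peak of any list.

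The grouping, tests, thresholds, most alternatives and the naming rule were fixed before the data were examined. The rule names METTL7A, EGFR, MET and MYC whatever their values, the 3 bins of 1 Mb with most peaks per list and, with no annotation of the peaks' build, the 10 highest peaks of a list by position. Other loci named were chosen after their values were seen. No GRCh37 annotation was used. Gene names at a position come from general knowledge of that build and are given to the locus only, and "gene start" means a peak at the 5′ end of the gene. The GRCh38.p14 table served for gene names and neighbours, with none of its coordinates printed. The planned share of peaks at promoters, the test of 14 gene lists and the share of peaks with an E-box were not run, since each needs GRCh37 sequence or annotation.

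Alternatives were a global IDR of 0.01, all matched peaks, the interval of either replicate alone, removal of chromosome 7, an overlap of 50% of both peaks, the 200 bp around the summit, placement over the whole genome and other sets of control lists. After the data were seen, placement within 500 kb of each peak, control lists with all matched peaks, peaks with −log10 p of at least 9 or 5, ranking by one replicate, reproducible peaks for the 10 regions, heights within each wild-type list and the Wald test were added. The overlap code was tested on simulated positions at the size of the comparison of resistant METTL7A with resistant wild-type MYC-tag peaks (3165 peaks, 40 simulations). Random lists gave p under 0.05 in 5.0% of runs, and 30 planted overlaps were called in 100.0% of runs with a mean excess of 30.2. The simulated positions were spread at random within each chromosome, as the placements assume. These rates therefore do not extend to clustered peaks or shorter lists, and the tests of shares were not simulated. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.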

Results

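Peak lists from 8 groups of HCC827 cells were compared, each combining 2 replicates that the labels call biological. The groups crossed cell state (parental or osimertinib-resistant), genotype (wild-type or METTL7A-MYC-FLAG) and antibody (IgG or MYC-tag). Lists held 70 to 3165 matched peaks, of which 13 to 145 were reproducible. The depth of each library is unknown from the files, so a longer list may reflect a deeper or better enriched library as well as more bound positions. Spearman's rank correlation between the 2 replicates' −log10 p across the matched peaks of a list lay between −0.0305 (parental METTL7A IgG) and 0.435 (resistant METTL7A IgG). Those peaks are not independent replicates.

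The region around EGFR, the receptor tyrosine kinase gene that drives this tumour line, held most of the reproducible peaks in all 4 MYC-tag lists and in 2 of the 4 IgG lists. At 54 to 56 Mb of chromosome 7, which also holds VSTM2A, SEC61G, LANCL2 and VOPP1, lay 69.2% (95% interval 48.2 to 85.7) of the 26 reproducible MYC-tag peaks of parental wild-type cells and 51.6% (33.1 to 69.8) of the 31 IgG peaks. In parental METTL7A-expressing cells the region held 61.4% (52.9 to 69.3) of 145 MYC-tag peaks and 7.55% (2.09 to 18.2) of 53 IgG peaks. In resistant wild-type cells it held 58.7% (45.6 to 71.0) of 63 MYC-tag peaks and 45% (23.1 to 68.5) of 20 IgG peaks. In resistant METTL7A-expressing cells the shares were 66.3% (56.4 to 75.3) of 104 and 61.5% (31.6 to 86.1) of 13. The region makes up 0.0686% of the genome's span. A second cluster lay at 57 to 59 Mb of chromosome 12, which holds the cell-cycle kinase gene CDK4 with ARHGEF25, B4GALNT1 and AGAP2. It contributed 3 to 14 reproducible peaks in the 4 MYC-tag lists. Wild-type IgG had similar shares there, with 4 of 31 peaks (12.9%) in parental and 2 of 20 (10%) in resistant cells. The wild-type MYC-tag lists had 3 of 26 (11.5%) and 9 of 63 (14.3%), and the METTL7A IgG lists 0 of 53 and 0 of 13. A further cluster, at 11 to 12 Mb of chromosome 6 around TMEM170B and ADTRP, held 13 reproducible peaks in the parental METTL7A MYC-tag list, 8 of 104 (7.69%) in the resistant one, 5 of 63 (7.94%) in resistant wild-type MYC-tag and 1 in each resistant IgG list.

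**Figure D1:**
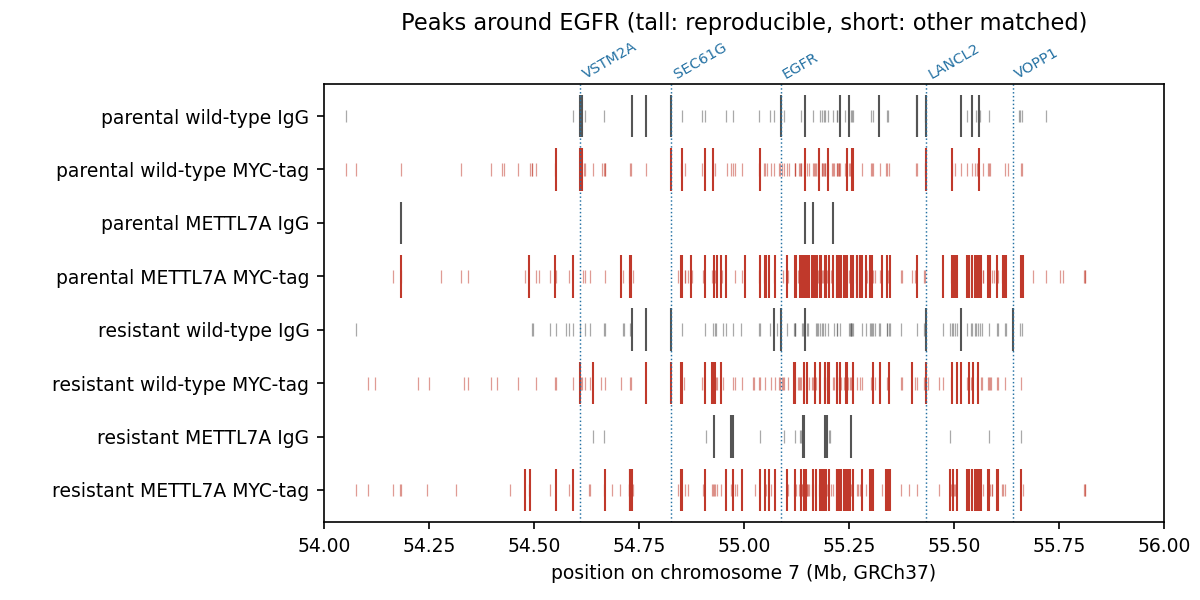
Peaks around EGFR, by position on chromosome 7 (Mb, GRCh37), in the 8 lists, with red marks for MYC-tag, grey marks for IgG, tall marks for reproducible peaks and short marks for other matched peaks; dotted lines mark gene starts. The parental and resistant METTL7A MYC-tag lists have 89 and 69 reproducible peaks here, and the wild-type IgG lists have 16 and 9.

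The first comparison asked how far MYC-tag peaks stood apart from the IgG background of the same cells. The start of LANCL2, a gene neighbouring EGFR, held the highest MYC-tag peak of parental wild-type cells (7:55433138–55434657, −log10 p 15.6), and the IgG list of the same cells had a peak there of 13.9. The SEC61G start, at a gene of the protein translocation channel, was highest in the IgG list (7:54826493–54827120, 20.8) and reached 14.1 in the MYC-tag list. Further high parental wild-type MYC-tag peaks lay at the start of B4GALNT1, a ganglioside synthase gene (12:58025479–58027161, 14.3), of TBK1, an innate immune kinase gene (12:64845642–64846409, 12.6), of CDK4 (12:58145799–58146522, 12.4) and of RDH10, a retinol dehydrogenase gene (8:74206075–74207721, 10.4). In resistant METTL7A-expressing cells the highest MYC-tag peak lay in the first intron of EGFR (7:55145228–55147646, 35.9), a position with a matched peak in 7 of the 8 lists. Next came CDK4 (12:58145769–58146554, 26.3), with a matched peak in 5 lists. A peak in ADTRP, a fatty acid ester hydrolase gene (6:11770563–11772103, 19.7), also had a match in the IgG list of those cells.

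Wild-type cells gave 26 reproducible MYC-tag and 31 IgG peaks in the parental state (ratio 0.839), and 63 and 20 in the resistant state (3.15). METTL7A-expressing cells gave 145 and 53 (2.74) and 104 and 13 (8). Among matched peaks the ratios were 0.696 and 1.09 in wild-type cells, and 32.4 and 33.0 in METTL7A-expressing cells, whose IgG lists held 70 and 96 matched peaks against 1444 and 2529 in wild-type cells. Among peaks of −log10 p 9 or more in both replicates the resistant wild-type ratio turned to 0.495 (48 and 97), while the parental wild-type one was 1.42 (27 and 19). At that threshold METTL7A-expressing cells gave 133 MYC-tag peaks and 1 IgG peak in the parental state, and 98 and 3 in the resistant state. The reproducible peaks of these IgG lists reach down to −log10 p 3.18 and 4.98. Heights are not on a common scale across lists and depths are unknown, so counts at one threshold can also differ with the libraries. In parental wild-type cells 8 of 26 reproducible MYC-tag peaks (30.8%, 14.3 to 51.8) overlapped an IgG peak. In parental METTL7A-expressing cells 4 of 145 did (2.76%, 0.757 to 6.91), in resistant wild-type cells 6 of 63 (9.52%, 3.58 to 19.6) and in resistant METTL7A-expressing cells 3 of 104 (2.88%, 0.599 to 8.20). The METTL7A IgG lists behind the lower values held 53 and 13 reproducible peaks. Against the 4 IgG lists joined, the overlaps were 9 of 26 (34.6%) and 18 of 145 (12.4%) in parental wild-type and METTL7A-expressing cells, and 19 of 63 (30.2%) and 12 of 104 (11.5%) in resistant ones. For the IgG list of the same cells random placement gave means of 0.006 to 0.01 overlapping peaks, and each of the 4 one-sided permutation tests had an adjusted p of 0.001, the smallest the placements can give. Placement within 500 kb gave 0.506 to 0.827 overlapping peaks by chance, with adjusted p-values of 0.00266 in 3 of the permutation tests and 0.05, after rounding up, in resistant METTL7A-expressing cells. The 4 overlaps in parental METTL7A-expressing cells lay on chromosome 7, and none was left once that chromosome was removed. No reproducible overlap was left in resistant METTL7A-expressing cells at a global IDR of 0.01, where the IgG list held 3 peaks. Over matched peaks the EGFR region held a larger share of MYC-tag than of IgG peaks in parental wild-type cells, which lack the tag (12.7% against 4.16%, odds ratio 3.35, Fisher exact test, adjusted p = 6.64e-13). In resistant METTL7A-expressing cells it held a smaller share of a longer list, though more peaks (153 of 3165, 4.83%, against 21 of 96, 21.9%, odds ratio 0.179, exact test, adjusted p = 4.53e-07). Among reproducible peaks neither passed (2.04 and 1.27, exact test, adjusted p = 1), and parental METTL7A-expressing cells did (17.4, adjusted p = 1.57e-10). That call rests on an IgG list of 53 reproducible peaks, which reach down to a −log10 p of 3.18 and make up 75.7% of its matched peaks. Over matched peaks the same pair did not pass (7.27% against 5.71%, odds ratio 1.16). In resistant wild-type cells the odds ratio was 1.21 over matched peaks (exact test, adjusted p = 0.650), and 2.54, 1.40 and 2.51 at a −log10 p of 5 or more in both replicates, the first or the second (adjusted p = 6.19e-08, 0.106 and 7.32e-09).

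**Figure D2:**
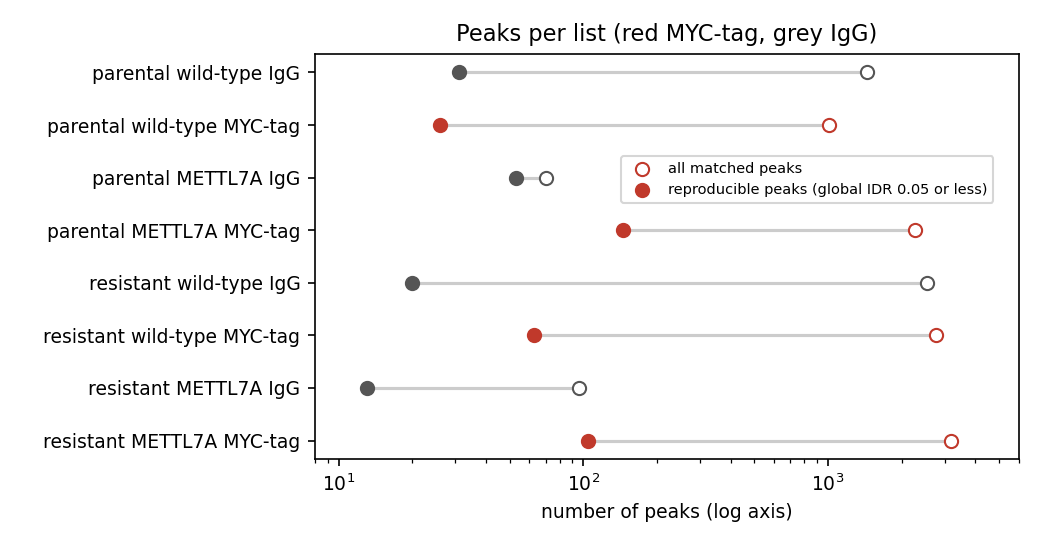
Number of peaks per list on a log axis, for 8 lists that each combine 2 replicates; open circles are all matched peaks, filled circles are reproducible peaks, red is MYC-tag and grey is IgG. The IgG lists of METTL7A-expressing cells hold 70 and 96 matched peaks, and every other list holds at least 1005.

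The second comparison asked which MYC-tag peaks appeared with the tagged METTL7A. The highest nuclear peak of the parental METTL7A MYC-tag list lay upstream of EGFR (7:55057950–55059451, −log10 p 24.2). It had a matched peak in the resistant METTL7A MYC-tag list (14.5) and in none of the other 6 lists. A similar pair lay beyond the 3′ end of the main EGFR transcript (7:55299054–55300076, 12.3 parental and 11.2 resistant). Other such pairs lay near TMEM170B (6:11634269–11634777, 11 and 11.1), in the pericentromere of chromosome 21 (21:10610418–10610856, 8.74 and 11.8) and in the CDK4 region (12:57984755–57985619, 7.78 and 10.1). The highest resistant wild-type MYC-tag peaks included the start of VSTM2A (7:54609560–54610354, 23.1), a gene of an immunoglobulin-domain protein, and a position in AGAP2, a GTPase-activating protein gene (12:58119244–58122062, 20.5) that also had matched peaks in both METTL7A MYC-tag lists.

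METTL7A-expressing cells had 5.58 times as many reproducible MYC-tag peaks as wild-type cells in the parental state (145 and 26) and 1.65 times as many in the resistant state (104 and 63). Among matched peaks the ratios were 2.26 and 1.14, and at a −log10 p of 9 or more in both replicates 4.93 and 2.04. Outside the EGFR region the counts were 56 and 8 in parental cells and 35 and 26 in resistant cells. A wild-type MYC-tag peak overlapped 10 of the 145 parental METTL7A peaks (6.90%, 3.36 to 12.3) and 25 of the 104 resistant ones (24.0%, 16.2 to 33.4). Both one-sided permutation tests had an adjusted p of 0.001, the smallest possible, and placement within 500 kb of each peak gave 3.11 and 5.92 overlapping peaks by chance. Such placement keeps peaks near EGFR but spreads the cluster, here and in the other comparisons. Its chance overlap may thus be too low, and overlap from clustering alone is not excluded. Of the parental METTL7A MYC-tag peaks 86.2% (79.5 to 91.4) were METTL7A-specific, with 74 of them in the EGFR region. Of the resistant ones 75 (72.1%, 62.5 to 80.5) were specific, 47 of them in that region. Set against all matched peaks of the control lists, 69 (47.6%) and 27 (26%) stayed specific, and the EGFR region held 35 and 9 of these. Over matched peaks that region's share was lower for METTL7A than for wild-type MYC-tag in parental cells (7.27% against 12.7%, odds ratio 0.537, Fisher exact test, adjusted p = 1.79e-05). The resistant odds ratio was 0.960, and those among reproducible peaks were 0.728 (parental) and 1.38 (resistant), each with an adjusted p of 1 in the exact test. With peaks of −log10 p 5 or more in both replicates, the first or the second, the resistant share was lower for METTL7A (0.469, 0.683 and 0.567, exact test, adjusted p = 3.21e-06, 0.0261 and 0.000376), so the resistant call depends on the peaks counted. The highest specific peaks of parental cells lay on mitochondrial DNA, led by MT-CO1, a cytochrome oxidase gene (MT:5971–6801, 109). The first and the second replicate in the file gave 109 and 537 there, and no other list but the resistant METTL7A IgG list held a mitochondrial peak.

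The third comparison asked whether resistant and parental cells shared positions. The EGFR first intron peak, the LANCL2 start and the TBK1 start were in both wild-type states, with TBK1 at −log10 p 12.6 in the parental and 18.3 in the resistant MYC-tag list. The CDK4 start was in all 4 MYC-tag lists. Reproducible MYC-tag peaks of parental METTL7A-expressing cells recurred in resistant ones in 63 of 145 cases (43.4%, 35.2 to 51.9), and those of wild-type cells in 15 of 26 (57.7%, 36.9 to 76.6). For IgG the overlaps were 10 of 31 in wild-type cells (32.3%, 16.7 to 51.4) and 2 of 53 in METTL7A-expressing cells (3.77%, 0.460 to 13). Placement by chance gave 0.001 to 0.136 overlapping peaks, and each of the 4 one-sided permutation tests had an adjusted p of 0.001, the smallest possible. Placement within 500 kb gave 13.3 for METTL7A and 1.39 for wild-type MYC-tag, and 0.346 and 0.035 for wild-type and METTL7A IgG, with the same adjusted p in the permutation tests. Of the METTL7A-specific peaks, 37 parental ones overlapped specific peaks of resistant cells, and 7 did with control lists of all matched peaks.

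The long arm of chromosome 7 around MET, a receptor tyrosine kinase gene amplified in some osimertinib-resistant tumours, held a larger share of matched peaks in resistant cells. At 85 to 120 Mb lay 2.46% (1.91 to 3.11) of resistant wild-type MYC-tag peaks and 0.299% (0.0616 to 0.870) of parental ones (odds ratio 7.27, Fisher exact test, adjusted p = 1.79e-05). For METTL7A MYC-tag the shares were 2.05% (1.59 to 2.61) and 0.396% (0.181 to 0.751; odds ratio 5.03, adjusted p = 8.65e-07), and for wild-type IgG 2.45% (1.88 to 3.13) and 0.762% (0.381 to 1.36; odds ratio 3.16, adjusted p = 0.000846), by the same exact test. The METTL7A IgG lists had 5 of 96 and 1 of 70 peaks there (odds ratio 2.79, exact test, adjusted p = 0.901). The tests are two-sided, and the region was chosen after its values were seen. Among reproducible peaks the resistant and parental counts there were 0 of 20 and 0 of 31 (wild-type IgG), 2 of 63 and 0 of 26 (wild-type MYC-tag), 0 of 13 and 1 of 53 (METTL7A IgG), and 3 of 104 and 0 of 145 (METTL7A MYC-tag). None of these 4 pairs passed the threshold (exact test, adjusted p = 1). In the EGFR region the share of matched peaks was instead lower in resistant than in parental cells for wild-type MYC-tag (5.02% against 12.7%, odds ratio 0.362, exact test, adjusted p = 6.64e-13) and METTL7A MYC-tag (4.83% against 7.27%, 0.649, adjusted p = 0.00214). For wild-type IgG the share was about the same (4.19% against 4.16%, odds ratio 1.01). For METTL7A IgG it was higher (21.9% against 5.71%, 4.21, exact test, adjusted p = 0.0366). That call ended at a −log10 p of 5 or more in both replicates (7.67, 18 against 2 peaks in the lists, exact test, adjusted p = 0.653) or the first (1.18, adjusted p = 1), and held in the second (25.9, adjusted p = 0.0315). The wild-type MYC-tag count in the region was higher in resistant cells, at 139, while the list as a whole grew from 1005 to 2767. For METTL7A MYC-tag the count went from 165 to 153, and the list grew from 2271 to 3165. Among reproducible peaks the wild-type and METTL7A MYC-tag odds ratios were 0.650 and 1.24 (exact test, adjusted p = 1 for both), and the METTL7A IgG one was 17 (adjusted p = 0.004). The last compares 13 resistant with 53 parental peaks, the latter 75.7% of the matched peaks of their list. With only peaks of −log10 p 5 or more in both replicates, the IgG odds ratio of the MET arm was 5.33 with an adjusted p of 0.0787.

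**Figure D3:**
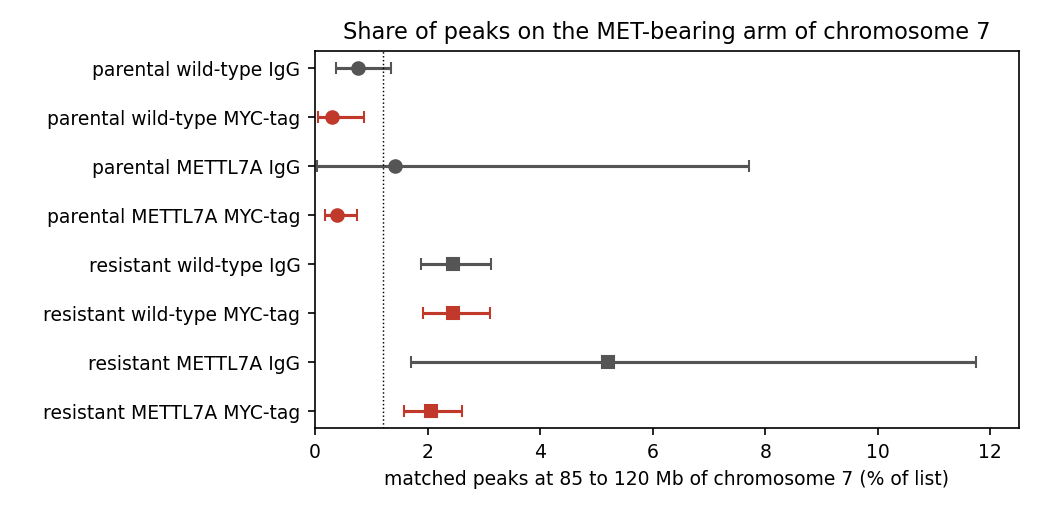
Share of matched peaks at 85 to 120 Mb of chromosome 7, in percent of each list, with exact 95% binomial intervals; circles are parental, squares are resistant, red is MYC-tag, grey is IgG, and the dotted line is the region's share of the genome's span (1.20%). The wild-type and METTL7A MYC-tag shares are 2.46% and 2.05% in resistant cells and 0.299% and 0.396% in parental cells.

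MET itself carried no reproducible peak in any of the 8 lists. Its 1 Mb bin held 5, 8, 0 and 9 matched peaks in the resistant wild-type IgG, wild-type MYC-tag, METTL7A IgG and METTL7A MYC-tag lists, and 2, 1, 0 and 0 in the parental ones. The difference between the METTL7A MYC-tag lists (odds ratio 13.7) had an adjusted p of 0.0919 in a two-sided Fisher exact test. Within MET lay matched peaks of resistant METTL7A MYC-tag (7:116363853–116364626, −log10 p 7.04), resistant wild-type MYC-tag (7:116381326–116381714, 5.69) and resistant wild-type IgG (7:116370075–116370430, 4.43). The highest peak of the bin lay at the start of CAV1, the caveolin gene, in resistant wild-type IgG (7:116164727–116166478, 11.7). The MYC gene, whose protein shares the epitope of the tag, had matched peaks in 4 of 4 MYC-tag lists and 0 of 4 IgG lists at 8:128747248–128751746. Their highest −log10 p values were 9.07 in parental METTL7A, 7.29 in resistant METTL7A, 5.10 in resistant wild-type and 3.39 in parental wild-type cells. The bounds of that interval are those of parental METTL7A MYC-tag peaks, so its choice partly set the count of MYC-tag lists. The METTL7A IgG lists held only 70 and 96 matched peaks, so their lack of a peak there says little. None of the MYC peaks was reproducible, the lowest global IDR being 0.0702. METTL7A had no matched peak in any list.

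The fourth comparison took chromosome 7, which carries EGFR and MET, as a whole. Of reproducible MYC-tag peaks, 73.1% (52.2 to 88.4) lay there in parental wild-type, 63.4% (55.1 to 71.3) in parental METTL7A, 61.9% (48.8 to 73.9) in resistant wild-type and 71.2% (61.4 to 79.6) in resistant METTL7A cells. For IgG the shares were 51.6% (33.1 to 69.8), 11.3% (4.27 to 23.0), 50% (27.2 to 72.8) and 61.5% (31.6 to 86.1), against 5.44% of the span. Of 8 two-sided Fisher exact tests, 2 passed. MYC-tag exceeded IgG in parental METTL7A-expressing cells (odds ratio 12.6, exact test, adjusted p = 1.74e-10), and resistant exceeded parental cells for METTL7A IgG (11.3, adjusted p = 0.00164). The other 6 odds ratios lay between 0.620 and 2.44, with adjusted p-values of 0.297 to 1. Both calls involve the parental METTL7A IgG list, whose reproducible peaks reach down to a −log10 p of 3.18. In that list 53 of 70 matched peaks (75.7%) were reproducible, against 0.791% to 13.5% in the other lists. Yet the rank correlation between its replicates was −0.0305, so its IDR selection may not be comparable with that of the other lists. Over all matched peaks the first odds ratio was 1.43 (exact test, adjusted p = 0.514), and the other was 3.70 (adjusted p = 0.0033). Ranked by the first or the second replicate the other was 7.15 and 7.64 (exact test, adjusted p = 0.0153 and 0.0203). At a global IDR of 0.01 it was 1.04 (exact test, adjusted p = 1), from 0 of 3 against 6 of 53 peaks, too few to judge. The odds ratio of MYC-tag against IgG in parental METTL7A-expressing cells was 5.17 times (95% Wald interval 1.27 to 21.1) that in wild-type cells, which Zelen's two-sided exact test put at p = 0.0273 and adjusted p = 0.0546 over both cell states. A Wald test of the same ratio, run before the exact test replaced it, gave an adjusted p of 0.0438, so the call depends on the test. It also depends on the peaks counted. Over all matched peaks the parental ratio was 0.767 (0.345 to 1.70, exact test, adjusted p = 0.651). Ranked by the first or the second replicate it was 3.69 and 14.8 (exact test, adjusted p = 0.150 and 0.000280). In resistant cells the ratio was 0.980 (0.214 to 4.49, exact test, adjusted p = 1). Ranked by the first or the second replicate it was 0.670 and 2.32 (exact test, adjusted p = 0.701 and 0.429). It was 0.279 (0.173 to 0.450, exact test, adjusted p = 2.33e-06) over all matched peaks. At a global IDR of 0.01 it could not be judged, since 0 of only 3 METTL7A IgG peaks lay on chromosome 7.

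**Figure D4:**
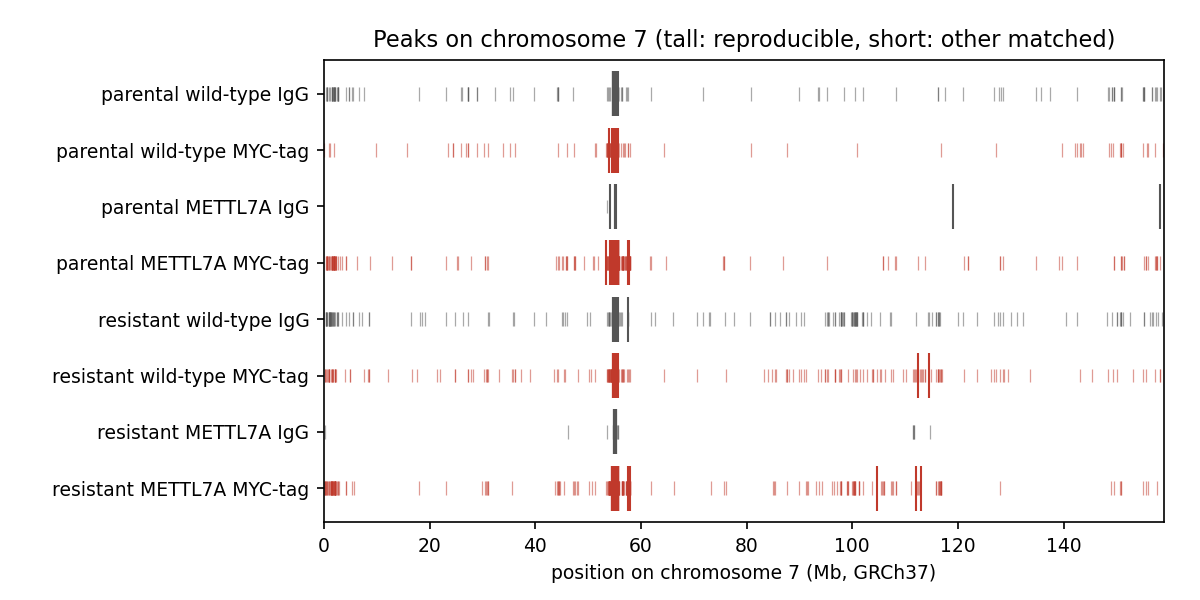
Peaks along chromosome 7 (Mb, GRCh37) in the 8 lists, with red marks for MYC-tag, grey marks for IgG, tall marks for reproducible peaks and short marks for other matched peaks. Reproducible peaks crowd at 54 to 56 Mb, and matched peaks at 85 to 120 Mb number 62, 68, 5 and 65 in the resistant lists from top to bottom, against 11, 3, 1 and 9 in the parental lists.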

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

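Placement within 500 kb, control lists with all matched peaks, −log10 p thresholds of 9 and 5, ranking by one replicate, reproducible peaks for regions, heights within each list and the Wald test were chosen after the results were seen; the other alternatives were planned. Of 101 alternative values for overlaps, 99 kept their direction and their side of the threshold. This says little for reproducible peaks placed along the chromosome, where the main setting gave at most 0.136 overlapping peaks by chance. Almost any overlap then passed, such as 1 of 30 resistant METTL7A MYC-tag peaks with IgG without chromosome 7 (permutation test, adjusted p = 0.00133). The overlap of METTL7A MYC-tag with IgG peaks fell to 0% in parental cells without chromosome 7 and to 0% in resistant cells at a global IDR of 0.01. In these cases fewer peaks were compared.

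In the order parental wild-type IgG, wild-type MYC-tag, METTL7A MYC-tag, then resistant wild-type IgG, wild-type MYC-tag, METTL7A IgG and METTL7A MYC-tag, a global IDR of 0.01 left 20, 0, 80, 7, 12, 3 and 65 peaks. All matched peaks gave 1444, 1005, 2271, 2529, 2767, 96 and 3165. In the parental METTL7A IgG list, left out of this order, 53 of 70 matched peaks stayed at a global IDR of 0.01. Only 2 of the 70 had a −log10 p of at least 5 in both replicates. A −log10 p of at least 9 in both replicates left 19 and 97 wild-type and 1 and 3 METTL7A IgG peaks in parental and resistant cells. METTL7A-specific peaks numbered 73 (parental, IDR of 0.01), 2052 and 2804 (parental and resistant, all matched peaks), 48 and 23 (without chromosome 7), and 69 and 27 (control lists with all matched peaks); 11 other values stayed within 1.5 times.

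For the share on chromosome 7, all matched peaks turned the odds ratio of resistant against parental METTL7A MYC-tag to 0.741 and that of MYC-tag against IgG in resistant METTL7A-expressing cells to 0.287. With the same peaks 3 others passed the threshold: 0.531 (resistant against parental wild-type MYC-tag), 1.87 (MYC-tag against IgG, parental wild-type) and 0.279 (resistant ratio of odds ratios). MYC-tag against IgG in parental METTL7A-expressing cells (1.43) no longer passed, nor did resistant against parental METTL7A IgG at an IDR of 0.01 (1.04, resting on 0 of 3 peaks). The parental ratio of odds ratios (5.17) passed by a Wald test only, was 0.767 over all matched peaks, and ranged from 3.69 to 14.8 when ranked by one replicate, where only the higher value passed. Another 24 odds ratios kept their side. In the 10 regions, −log10 p thresholds of 5 ended 2 calls each at 85 to 120 Mb of chromosome 7 (wild-type IgG), in its pericentromere, in the TMEM170B region and in the EGFR region (METTL7A IgG). They made 5 new calls in the EGFR region (resistant METTL7A against wild-type MYC-tag 0.469, 0.683 and 0.567; resistant wild-type MYC-tag against IgG 2.54 and 2.51), 2 in the TMEM170B region (the latter pair, 3.24 and 3.69) and 1 at 85 to 120 Mb (0.443, resistant METTL7A against wild-type MYC-tag). With reproducible peaks only, 3 calls at 85 to 120 Mb, 1 in the pericentromere, 2 in the TMEM170B region and 3 in the EGFR region ended, and 1 was new (17.4, EGFR region, parental METTL7A MYC-tag against IgG). There the EGFR region's odds ratio turned to 1.24 for resistant against parental METTL7A MYC-tag and to 1.27 for MYC-tag against IgG in resistant METTL7A-expressing cells. The cause was not tested.

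No paired analysis was possible because the replicate columns of a list cannot be matched to replicate numbers and each result comes from a list that combines replicates; the replicate block was not run. The alternatives for promoters, gene lists and E-boxes were also not run. With 0 parental wild-type MYC-tag peaks at an IDR of 0.01, the tests that need that list gave no value. Depth limits absence: library depths are unknown, so a position missing from a list is not shown to be unbound.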

Other observations

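The tests below were all chosen after the positions were seen. Over the 8 lists, matched peaks merged into 11138 positions, 42 of them in at least 6 lists. Of these, 34 lay in the EGFR region, 6 in the CDK4 region, 2 in the TMEM170B region and 0 elsewhere. A peak in the first intron of EGFR (7:55145167–55147646) was in 7 lists. Beyond these clusters, HBB, the beta-globin gene (11:5246136–5247333), had reproducible IgG peaks in parental wild-type (−log10 p 13.1) and resistant METTL7A-expressing cells (13), and a matched MYC-tag peak in the latter (5.98). In parental METTL7A-expressing cells its IgG peak was also reproducible (global IDR 0.000822), with 4.63 and 48.8 in the first and the second replicate in the file.

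In the pericentromere of chromosome 7, at 57 to 58 Mb, METTL7A MYC-tag lists held 26 (parental) and 28 (resistant) matched peaks, and wild-type MYC-tag lists 3 and 4. The difference passed the threshold in resistant cells (odds ratio 5.58, adjusted p = 0.000791, two-sided Fisher exact test) and not in parental cells (3.38, adjusted p = 0.0985). Among resistant peaks of −log10 p 5 or more in both replicates the odds ratio was 2.75, no longer past it. In the TMEM170B region, parental wild-type MYC-tag exceeded IgG (1.39% against 0.139% of matched peaks, odds ratio 8.44, exact test, adjusted p = 0.00187). Among METTL7A MYC-tag peaks the region's share was lower in resistant than in parental cells (0.948% against 1.85%, 0.510, exact test, adjusted p = 0.0446). This last call ended at a −log10 p of 5 or more in both replicates or in the second. Among reproducible peaks none of these calls passed: 2 of 104 against 0 of 63 in the pericentromere, and 0 of 26 against 0 of 31 and 8 of 104 against 13 of 145 in the TMEM170B region (exact test, adjusted p = 1).

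Reproducible peaks concentrated near EGFR, at 54 to 56 Mb of chromosome 7. Binding of the tagged METTL7A as the whole cause is argued against by wild-type cells, which lack the tag: the lower of their 2 MYC-tag shares was 58.7%. Amplified EGFR DNA, or another source that needs no tag, may account for much of the concentration, since the lowest share over the 4 wild-type lists, IgG included, was 45%, against 0.0686% of the span. The IgG share of parental METTL7A-expressing cells was 7.55% (2.09 to 18.2) among reproducible peaks, which reach down to a −log10 p of 3.18 in that list. Over matched peaks it was 5.71% (the same 4 peaks, of 70). Matched shares were 4.16% and 4.19% for parental and resistant wild-type IgG, of 1444 and 2529 peaks, and 21.9% of 96 for resistant METTL7A IgG. With such unequal lengths the closeness of some shares says little. How many of the METTL7A-specific peaks there come from such a source stays open, because no input signal was analysed here.

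Of 54 positions found in all 4 wild-type lists, 16 (29.6%) were in no METTL7A list, among them the starts of EGFR (7:55085275–55088472), VSTM2A, SEC61G, LANCL2, TBK1 and TMEM170B, and, lower, of BCL2L11 (2:111877865–111878884, −log10 p 4.63), which encodes the pro-apoptotic protein BIM. Since the METTL7A IgG lists held only 70 and 96 matched peaks, this absence rests mainly on the METTL7A MYC-tag lists. Differences ran both ways. In both METTL7A MYC-tag lists and no wild-type list were 230 positions, and 73 were in both wild-type MYC-tag lists and no METTL7A list. Weak peaks missed by chance stay open: by the highest of the 4 heights, the 16 had a median −log10 p of 16.6 and the other 38 one of 10.1 (two-sided permutation test, p = 0.00934). Within single lists this held for resistant IgG (14.5 against 7.96, permutation test, adjusted p = 0.000880) and not for the other 3 (adjusted p of 0.395 to 0.885). METTL7A expression and any difference in chromatin or library preparation between the genotypes, which the labels do not describe, cannot be told apart, because genotype alone parts these lists.

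Resistant lists held a larger share of matched peaks at 85 to 120 Mb of chromosome 7, around MET. The tag or its antibody as the whole cause is argued against by the wild-type IgG lists (odds ratio 3.16). Among METTL7A MYC-tag peaks of −log10 p 5 or more in both replicates the odds ratio was 4.35 (28 of 1246 against 4 of 840, exact test, adjusted p = 0.00852). For wild-type MYC-tag that odds ratio, 25.6, rests on 0 parental peaks (27 of 547 against 0 of 242, exact test, adjusted p = 0.000742). In the MYC-tag lists the larger share was thus not confined to peaks below that height. Longer or deeper lists stay open as a cause, because depths are unknown and heights are not on a common scale across lists. More DNA copies of the region in resistant cells may account for the larger share. It was higher in 4 of the 4 pairs of antibody and genotype and past the threshold in 3. For wild-type IgG it did not pass at a −log10 p of 5 or more in both replicates (5.33, 30 of 989 against 1 of 252, exact test, adjusted p = 0.0787). Selection in osimertinib of cells with other chromatin in this arm stays open and was not tested.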
